A study of Mus musculus with 39 samples.

How the data were processed

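Total RNA from the inferior colliculus of 39 CBA/CaJ mice was hybridized as biotin-labelled cRNA to Affymetrix MOE430A arrays, 1 array per mouse, per the labels' protocols. Group (hearing status) and sex of each mouse were taken from the labels. Mouse numbers are unique, so no replicate of a group is paired with one of another group.

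The deposited series values are intensities, 1 per probe set and array, on a linear scale; the algorithm that made them is not given in the sources used here. Tested on the values, each array has a trimmed mean of 500.101 to 500.198 with 2 percent left out at each end, 0 values are below 0, and the median log2(value + 16) per array ranges from 7.373 to 7.907. The arrays were thus scaled to a common mean, and whether the background was also subtracted stays unknown. A second deposited table holds 33 probe sets picked by the authors, with RMA signal (intensity on a linear scale) per array, per the file headers; the RMA version is not given in the sources used here. From these signals the authors computed a group ratio to the young controls, deposited per probe set, which recomputation matched as 2 to the power of the mean log2 ratio of each mouse to the arithmetic mean of the 8 young controls. The authors also deposited a score per probe set, the signed fold change, which is minus 1 over the ratio where the ratio is below 1. The further sheets repeat the 39 signal columns or hold values derived from them, and 249 columns of per-sample values were not used here.

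Of 22690 probe sets, 64 array controls were left out and 22626 were tested. The annotation table gave 1 gene symbol for 20380, several for 691 and none for 1555, in all 12393 genes named by a single symbol. The identifiers of 20351 probe sets were found in the reference gene table, and 0 symbols changed. Pairwise correlations of the arrays (log2) ranged from 0.9243 to 0.9746.

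Values were analysed as log2(intensity + 16), as deposited and without further normalization between arrays. limma 3.58.1 in R 4.3.3 fitted group means with sex as a covariate to all 39 arrays (34 residual degrees of freedom, prior 5.58), with empirical Bayes moderation and a trend of the variance with the mean. Tests were 2-sided, p-values were adjusted by Benjamini-Hochberg over the 22626 probe sets, and the threshold was 0.05. The 6 pairwise group comparisons, an F-test across the groups, male minus female, and the sex by group interaction for middle-aged and mild mice were tested; the severe group holds 1 male, so its interaction was not tested. For 47 probe sets of GABA genes, p-values were also adjusted over the list alone. Intervals are at 95 percent.

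Lists of genes were tested with limma camera at a preset inter-gene correlation of 0.01, on the probe set with the highest mean for each gene, with Benjamini-Hochberg adjustment within each comparison over the 34 of 37 lists that had at least 3 measured genes. The called lists numbered 1 for middle-aged, 10 for mild and 8 for severe mice against young controls, 7 for mild and 8 for severe against middle-aged mice, and 4 for severe against mild. With an estimated correlation these numbers were 0, 4, 7, 4, 6 and 3, and with limma fry 0, 6, 8, 4, 7 and 2. The groups, comparisons, tests, lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The permutation test of list scores, without the sex covariate, was added after the data were seen. It used all splits for mild against young, severe against young and severe against mild mice, and 100000 resamples for the other comparisons.

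Genes are named by a rule. Among called probe sets with 1 symbol and a mean in the upper 60 percent of all probe sets, the 10 largest rises and the 10 largest falls are named, or the 3 smallest p-values in each direction where none was called. Any gene of the GABA lists and up to 4 genes of another list with the smallest p may be named as well. The number of mice that show a direction counts the mice of the first group on that side of the mean of the second.

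The alternatives were quantile normalization, centring of each array on its median, a pseudocount of 1 or 64, leaving out the 40 percent dimmest probe sets, no sex covariate, only the 2 groups compared, array weights, the mouse number as a covariate, no trend or a robust fit of the variance, plain probe sets only (those with no suffix for shared probes), each sex alone, the RMA table for the GABA genes, an estimated correlation or fry for the lists, the mean over probe sets of a gene, and leaving out each severe and each young mouse in turn. Chosen after seeing the data were leaving out middle-aged replicate 4, leaving out the 3 arrays with the highest cerebellar marker signal, a covariate of the 3' over 5' ratio of control probe sets, a covariate for a suffix in the array name (8 of 39 arrays), and the permutation of list scores.

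The fit was tested on simulated data with 200 changed probe sets among 22626. Changes of 1 log2 unit were called for 85.1 percent in middle-aged, 71.6 percent in mild and 62.7 percent in severe mice against young controls, and for 86.6, 76.1 and 73.1 percent in mild against middle-aged, severe against middle-aged and severe against mild mice. Changes of 0.5 log2 units against young controls were called for 35.8, 28.4 and 17.9 percent. Over the 6 comparisons 2 to 13 calls were false. The simulated noise was normal and independent between probe sets and arrays. Correlated genes and outlying arrays were thus left out, and these numbers are not the rate of false calls in the real data.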

Results

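Transcript levels were measured in the inferior colliculus, the main auditory centre of the midbrain, of 39 CBA/CaJ mice. This inbred strain is used to study hearing loss with age (presbycusis). Each mouse gave 1 Affymetrix MOE430A array. The 4 groups were 8 young adult controls (4 females, 4 males), 17 middle-aged mice with good hearing (10 females, 7 males), 9 mice with mild presbycusis (4 females, 5 males) and 5 mice with severe presbycusis (4 females, 1 male). Values were signal intensities of 22626 probe sets. The median intensity per array was 164 to 217 in young controls, 168 to 211 in middle-aged mice, 172 to 224 in mild presbycusis and 150 to 203 in severe presbycusis. Differences below are on the log2(intensity + 16) scale, which understates the change of dim genes. Each comes with its standard error (SE) from a linear model with sex as a covariate. The number of arrays, above all the 5 of the severe group, limits the precision. The ages of the mice are not given in the sources used here. Only the comparison of middle-aged with young mice has good hearing in both groups, and those with the presbycusis groups do not separate age from hearing loss.

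The title of the series concerns GABA receptors, the receptors of the main inhibitory transmitter of the brain. In all 47 probe sets of 31 genes for GABA receptor subunits, GABA synthesis and transport, and receptor trafficking were measured. The smallest p-values among them in severe presbycusis against young controls belonged to Gabra2 and Slc32a1. Gabra2, which encodes a GABA-A receptor subunit, differed by -0.85 (SE 0.30, 95% interval -1.46 to -0.25, lower than the young mean in 4 of 5 mice). Slc32a1, the vesicular GABA transporter, differed by -0.61 (SE 0.22, 95% interval -1.05 to -0.17, lower in 5 of 5; its other, dim probe set differed by 0.25). Neither passed, with an adjusted p of 0.183 for both over the list alone and of 0.333 and 0.353 over all probe sets. The synthetic enzymes Gad1 and Gad2 differed by -0.18 (SE 0.19) and -0.27 (SE 0.19), and the abundant receptor subunit Gabrb1 by -0.02 (SE 0.13). Of the 47 probe sets, 0 were called by limma in any of the 6 comparisons, over all probe sets or adjusted over the list alone. The counts at an unadjusted p under 0.05 were 0 for middle-aged, 3 for mild and 6 for severe mice against young controls. They were 0 for mild and 4 for severe against middle-aged mice, and 2 for severe against mild. Gabrg1, another receptor subunit (0.41, SE 0.17), and Zdhhc3, a palmitoyltransferase that acts on GABA-A receptors (-0.41, SE 0.16), had adjusted p of 0.253 and 0.228 over the list alone in severe against young mice. Gabarapl1, which encodes a relative of the GABA-A receptor-associated protein, had the widest difference (-1.20, SE 0.75) on 1 probe set, while its other probe set differed by 0.09 (SE 0.10). Without severe replicate 5 the Gabra2 difference was -1.13 and passed over the list alone (adjusted p 0.021). On the deposited RMA signals the same Gabra2 probe set differed by -0.14 (SE 0.07) in severe against young mice. By limma its adjusted p was 0.389 over the 33 deposited probe sets. Among females alone Gabrg1 passed in severe against young mice (0.76, adjusted p 0.0181) and in middle-aged against young mice (0.56), as did Nsf, of the trafficking genes, in the latter (-0.70, adjusted p 0.0329 for both). On the deposited RMA table Gabarap passed in severe against middle-aged mice (0.26, adjusted p 0.0474).

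**Figure D1:**
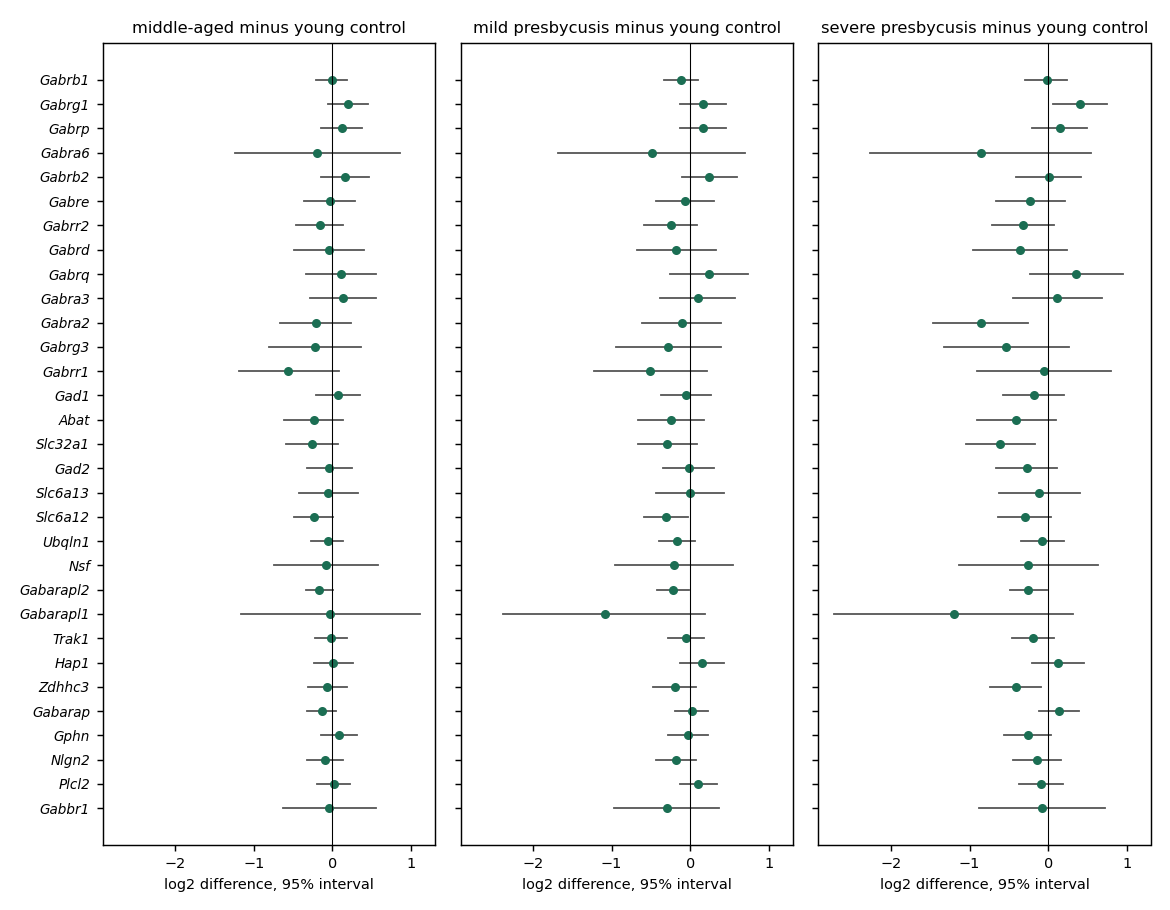
Log2 differences of 31 GABA genes (points, 1 probe set per gene) with 95% intervals (lines) in middle-aged, mild presbycusis and severe presbycusis mice against 8 young controls. None passed over the list alone. The points of severe presbycusis reach from -1.20 for Gabarapl1 to 0.41 for Gabrg1.

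As groups, the 6 measured genes of GABA synthesis, transport and breakdown were lower in severe presbycusis than in young controls (median -0.29, camera adjusted p 0.0184, and 0.0481 with an estimated correlation). All 6 were below 0 and none was called alone. In mild presbycusis the median of this list was -0.15 (adjusted p 0.0466, and 0.148 with an estimated correlation). The 11 genes of receptor trafficking and anchoring had a median of -0.17 (adjusted p 0.0348, and 0.0734 with an estimated correlation). The 13 measured GABA-A receptor subunits did not pass in any comparison. Their median was -0.05 in severe against young mice (adjusted p 0.56). The call of the synthesis list in severe presbycusis was lost without severe replicate 4 (median -0.30, adjusted p 0.087) or young replicate 1 (median -0.21, adjusted p 0.059). It was also lost among females alone (median -0.40, adjusted p 0.111) and with the 3' over 5' ratio of control probe sets as a covariate (adjusted p 0.0512). By permutation of the list scores its adjusted p was 0.11. In mild presbycusis it was lost without young replicate 1, 2, 6 or 8 (adjusted p 0.158, 0.0763, 0.106 and 0.0659). Over all alternatives the mild call of the synthesis list was lost in 15 of 34, with a median of 0.04 in males alone (adjusted p 0.755), and that of the trafficking list in 11 of 34. By permutation of the list scores both had an adjusted p of 0.31. The call of the trafficking list was lost without young replicate 3, 6 or 8 (adjusted p 0.0742, 0.0793 and 0.0659). The trafficking list did not pass in severe against young mice (median -0.19, adjusted p 0.075). It passed without severe replicate 3 (-0.23, adjusted p 0.0078) or young replicate 7 (-0.21, adjusted p 0.0465), by fry (adjusted p 0.0207), with array weights (adjusted p 0.0401) and with the array name suffix as a covariate (adjusted p 0.0293). Against middle-aged mice it passed without severe replicate 3 (-0.20, adjusted p 0.022).

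Gabra6, a receptor subunit known mainly from granule cells of the cerebellum, had the lowest ratios to young controls in the authors' deposited table. The authors' deposited ratios were 0.207 for middle-aged, 0.158 for mild and 0.136 for severe mice. In that authors' deposited table every named probe set other than those of Gabra6 and Gabrd lay between 0.884 and 1.20. On the array intensities Gabra6 averaged 8.36 ± 1.83 (SD, n = 8) in young controls, 8.17 ± 1.35 (n = 17) in middle-aged mice, 7.87 ± 0.59 (n = 9) in mild and 7.49 ± 0.68 (n = 5) in severe presbycusis. The differences from young controls of -0.19, -0.49 and -0.86 had SE of 0.52, 0.59 and 0.70. Young replicate 2 stood at 12.82, where the other 7 young mice lay between 7.40 and 8.32 with a mean of 7.73 ± 0.34 (SD). The same array carried high levels of other genes of the cerebellum. Car8, a Purkinje cell protein, lay 4.20 above the mean of the other young arrays, Cbln3, of granule cells, 4.19, and Pcp2, of Purkinje cells, 3.62. Pcp4 (-0.11) and Barhl1 (-0.50) were not raised on it. Without this array the Gabra6 differences from young controls were 0.50 (SE 0.42, 95% interval -0.36 to 1.36) in middle-aged, 0.15 (SE 0.47) in mild and -0.11 (SE 0.56) in severe mice. Their adjusted p were 1, 0.989 and 0.992. Middle-aged replicates 7 and 8 also carried cerebellar signal, with Gabra6 at 12.68 and 9.86. Without these and young replicate 2 the differences were 0.00 (SE 0.23, 95% interval -0.48 to 0.47) in middle-aged, 0.14 (SE 0.25) in mild and -0.29 (SE 0.30) in severe mice.

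**Figure D2:**
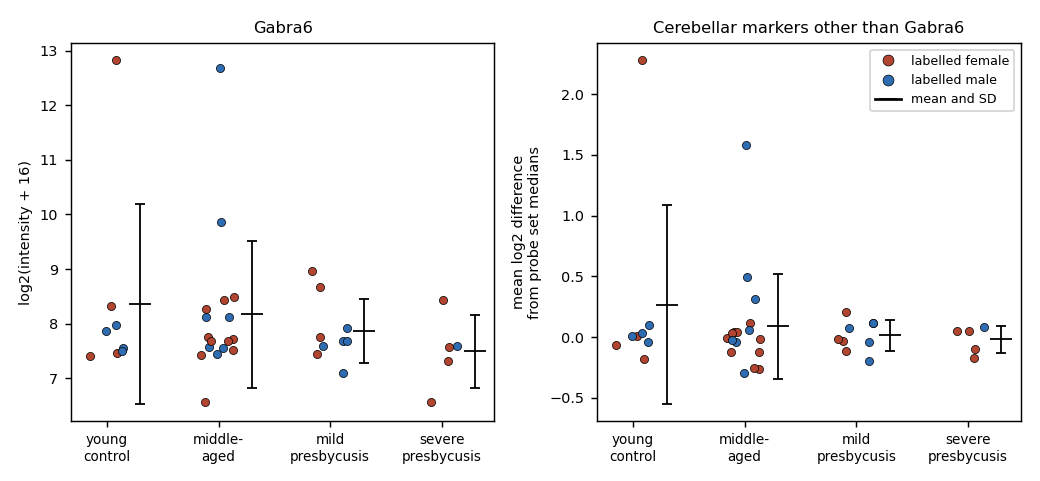
Gabra6 as log2(intensity + 16) and the mean log2 difference of the other cerebellar markers from their medians, 1 point per mouse (colour, sex), with mean and SD per group. Young replicate 2 stands at 12.82 for Gabra6 while the other young controls lie between 7.40 and 8.32.

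Middle-aged mice with good hearing were set against young controls to give the change with age before hearing loss. A single gene passed, Pcdhb9, a clustered protocadherin of neuronal cell adhesion. It rose by 0.58 (SE 0.09, adjusted p 0.0073) and was above the young mean in 17 of 17 mice, at mean intensities of 1460 against 987. Lists of microglia, complement and antigen presentation genes did not pass, with the complement gene C1qc at 0.25 (SE 0.23, adjusted p 0.998) and H2-D1 at 0.37 (SE 0.17, adjusted p 0.96). The 12 genes of fibroblasts, meninges and collagen were lower as a list (median -0.27, camera adjusted p 7.7e-05, but 0.411 with an estimated correlation), and none was called alone. Igf2, a growth factor of the meninges, differed by -1.82 (SE 0.44, adjusted p 0.76, lower in 16 of 17), Ogn, a small proteoglycan, by -1.25 (SE 0.36) and Fmod by -0.69 (SE 0.22). In total 1 of 22626 probe sets was called by limma and 1151 had an unadjusted p under 0.05, where chance gives 1131. The Pcdhb9 call was lost without young replicate 1 (0.51, adjusted p 0.0776) or 2 (0.52, adjusted p 0.0724), and with the arrays centred on their median (0.58, adjusted p 0.275). It was also lost among males alone, and over all alternatives the difference ranged from 0.35 to 0.78. Without young replicate 4 the count was 2.

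Mild presbycusis against young controls gave 38 called probe sets, all higher, of 31 named genes. Among the largest rises were Lyz1, a lysozyme (2.10, SE 0.43, adjusted p 0.0191), and Mpeg1, a pore-forming protein of macrophages (2.05, SE 0.26, adjusted p 9.08e-06). The Lyz1 probe set, here and in the comparisons below, carries a suffix for shared probes, so its signal may not be that of Lyz1 alone. The C1qb probe set used below also carries such a suffix, and Lyz1 and C1qb are not the only such cases. H2-D1, an MHC class I heavy chain, rose by 1.82 (SE 0.19, adjusted p 1.04e-07) and Rtp4, an interferon-induced chaperone, by 1.78 (SE 0.29, adjusted p 0.000751). Each was above the young mean in 9 of 9 mice, and Mpeg1 went from a mean intensity of 131 to 590. Laptm5, a lysosomal membrane protein of immune cells, rose by 1.11 (SE 0.22), Pcdhb9 by 1.02 (SE 0.11), the pattern receptor Clec7a by 0.91 (SE 0.15) and the chitinase-like Chil1 by 0.88 (SE 0.15), all in 9 of 9. C3ar1, the receptor of a complement fragment, rose on 1 probe set (1.05, SE 0.22) and did not pass on its brighter one (0.34, SE 0.14, adjusted p 0.637).

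By lists fixed in advance, 5 of 9 measured MHC class I presentation genes rose in mild presbycusis (list median 0.67, camera adjusted p 2.88e-13, and 2.36e-05 with an estimated correlation). Among them were H2-D1, the immunoproteasome subunit Psmb8 (1.44, SE 0.22), H2-K1 (0.67, SE 0.11) and the class I light chain B2m (0.86, SE 0.15). Of 16 microglia markers 3 rose on the brightest probe set of each gene (median 0.54, adjusted p 2.53e-11, and 9.08e-05 with an estimated correlation). They were Tyrobp (0.85, SE 0.17), an adaptor of microglial receptors, the Fc receptor Fcgr3 (0.65, SE 0.14) and the lysosomal protease Ctss (0.60, SE 0.13). Laptm5, named above, is also on this list and was not among these 3. Of 6 complement genes 2 rose (median 0.64, adjusted p 3.08e-08, and 0.00069 with an estimated correlation): C1qc by 1.76 (SE 0.26) and C1qb by 1.02 (SE 0.21). Of 12 interferon-stimulated genes 2 rose (median 0.34, adjusted p 3.08e-08, and 0.00382 with an estimated correlation), Ifit3 by 0.73 (SE 0.11) and Rtp4. The remaining list calls were lower and contained no called gene. They were those of the immediate early genes (16 genes, median -0.10, adjusted p 0.00849, and 0.222 with an estimated correlation; Fos -0.62, SE 0.25) and of oxidative phosphorylation (24 genes, median -0.09, adjusted p 0.000935, and 0.226 with an estimated correlation; Cox8a -0.87, SE 0.29). Lower too were fibroblast, meningeal and collagen genes (median -0.19, adjusted p 0.00849, and 0.30 with an estimated correlation) and cerebellar markers (14 genes, median -0.15, adjusted p 0.00849, and 0.335 with an estimated correlation). The cerebellar list had a median of 0.09 without young replicate 2 (adjusted p 0.939).

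The count of 38 fell to 24 without young replicate 2 or without young replicate 3. It was 464 among females alone and 7 among males alone. The rises of Lyz1 and C1qb were mainly those of females, with 3.77 and 1.79 among females alone against 0.62 (adjusted p 0.713) and 0.35 (adjusted p 0.747) among males alone. Of the called genes named above only H2-D1 passed among males alone (1.63, adjusted p 0.0143), with fewer mice than in the full comparison. The lists of MHC class I, microglia, complement and interferon-stimulated genes passed there (highest adjusted p 0.005, that of complement). Without 1 young mouse the calls of Lyz1 (replicates 1, 2 or 3, adjusted p 0.0602, 0.0535 and 0.0631), C3ar1 (replicates 1, 2, 3 or 6, up to 0.0659) and Fcgr3 (replicates 1, 2, 3 or 6, up to 0.0946) were lost. So were those of Ctss (replicates 2, 3 or 8, up to 0.0922), C1qb (replicate 3, 0.0631) and Tyrobp (replicate 4, 0.0503). With the arrays centred on their median the calls of Lyz1, C1qb, C3ar1, Ctss, Fcgr3 and Laptm5 were lost (adjusted p 0.0653, 0.0892, 0.0597, 0.0988, 0.234 and 0.085). With only these 2 groups in the fit those of Lyz1, C1qb, C3ar1, Ctss, Fcgr3, Tyrobp and B2m were lost (up to 0.37). Oxidative phosphorylation lost its call with quantile normalization (median -0.03, adjusted p 0.456). Among lists, leaving out 1 young mouse ended the calls of the immediate early genes (replicate 8, 0.0511) and the fibroblast list (replicates 6, 7 or 8, up to 0.0659). Serpina3n, a protease inhibitor of reactive astrocytes, did not pass (2.08, SE 0.48, adjusted p 0.0568). It passed among females alone (2.76, adjusted p 0.000308), with only these 2 groups in the fit (2.13, adjusted p 0.000979), with a pseudocount of 1 (adjusted p 0.0361), with the array name suffix as a covariate (adjusted p 0.0343) and without severe replicate 4 (2.07, adjusted p 0.045). The MHC class I call was lost on plain probe sets only, where its median was -0.04 (adjusted p 0.48). That setting leaves out probe sets with any suffix, so it does not tell which of them carried the rise.

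Severe presbycusis against young controls gave 120 called probe sets, 114 higher and 6 lower. Lyz1 rose by 3.84 (SE 0.52, adjusted p 8.7e-06), a fold of 14.4, on a probe set with shared probes. Mpeg1 rose by 3.43 (SE 0.31, adjusted p 2.27e-09), a fold of 10.8 from a mean intensity of 131 to 1960, and H2-D1 by 2.31 (SE 0.23, adjusted p 1.2e-08), each in 5 of 5 mice. The poly(A) polymerase Tent5c rose by 2.77 (SE 0.53), Clec7a by 1.84 (SE 0.18), and Rtp4 by 1.80 (SE 0.35). Ptprc, the leukocyte antigen CD45, rose by 1.48 (SE 0.18), the lysozyme Lyz2 by 1.46 (SE 0.34), C1qb by 1.44 (SE 0.24) and Chil1 by 1.38 (SE 0.18), all in 5 of 5. Among brighter probe sets the largest falls were those of Sez6l, a neuronal membrane protein (-0.65, SE 0.15), and Elmo1, a regulator of engulfment and cell migration (-0.63, SE 0.13). Lower too were the cell cycle protein Cks2 (-0.61, SE 0.15), the tetraspanin Tspan17 (-0.57, SE 0.13) and Slc7a10, a transporter of D-serine and other small amino acids (-0.51, SE 0.12), all 5 genes in 5 of 5 mice. The remaining lower call was that of the dimmer Hs1bp3 (-1.36, SE 0.32, adjusted p 0.0261), named after its values were seen. Of the 2 other Lyz1 probe sets 1 differed in the opposite direction. So did the other probe sets of Rtp4 and Elmo1 and 1 of the 8 others of H2-D1.

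The glial and immune lists moved with these genes. Of 16 microglia markers 9 rose (median 0.82, camera adjusted p 2.58e-25, and 5.15e-08 with an estimated correlation). Among them were Cd68 (1.30, SE 0.17), a lysosomal protein of phagocytes, Fcgr3 (1.27, SE 0.17), Cd53 (1.16, SE 0.16) and Tyrobp (1.36, SE 0.20). Of 6 complement genes 4 rose (median 1.07, adjusted p 2.67e-13, and 1.42e-05 with an estimated correlation), including C1qc (2.76, SE 0.31) and C1qa (2.08, SE 0.32). Of 9 MHC class I genes 4 rose (median 0.83, adjusted p 6.82e-13, and 1.42e-05 with an estimated correlation). Of 6 MHC class II genes H2-Aa rose (1.04, SE 0.21; list median 0.38, adjusted p 7.89e-05, and 0.0131 with an estimated correlation). Of 12 interferon-stimulated genes 2 rose, Ifit3 (0.90, SE 0.13) and Rtp4 (list median 0.61, adjusted p 1.48e-06, and 0.0106 with an estimated correlation). Of 12 astrocyte markers 2 rose (median 0.16, mean 0.65, adjusted p 7.89e-05, and 0.00127 with an estimated correlation). With dim probe sets left out the astrocyte call was lost (median 0.09, adjusted p 0.168). The protease inhibitor Serpina3n rose by 4.56 (SE 0.57, adjusted p 2.85e-06), from a mean intensity of 29.5 to 1190. The intermediate filament Gfap rose by 1.51 (SE 0.32, adjusted p 0.00793), both in 5 of 5 mice. Markers of oligodendrocytes (median 0.03, adjusted p 0.84), endothelium (median -0.09, adjusted p 0.84) and blood (median 0.03, adjusted p 0.465) did not pass. Immediate early genes were lower as a list (median -0.15, adjusted p 0.0334, but 0.365 with an estimated correlation). Fos stood at -0.95 (SE 0.30, adjusted p 0.231) and Nr4a1 at -0.67 (SE 0.22), below the young mean in 5 of 5 mice.

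The count of 120 was 43 when only these 2 groups entered the fit and 247 among females alone. In that fit of 2 groups the calls of Rtp4 (adjusted p 0.167), Tent5c (0.0756), Tyrobp (0.0568), Elmo1 (0.0893), Gfap (0.095), H2-Aa (0.193), Lyz2 (0.0667), C3ar1 (0.356), Sez6l (0.182), Cks2 (0.211), Tspan17 (0.113) and Slc7a10 (0.339) were lost. Of the MHC class I genes B2m (0.0862), H2-K1 (0.0681) and Psmb8 (0.191) lost their calls there too. Those of Elmo1, Sez6l and Slc7a10 were also lost with the arrays centred on their median (adjusted p 0.0809, 0.147 and 0.0607), and over all alternatives Sez6l lost its call in 14 of 30. The lists of MHC class I (median -0.04, adjusted p 0.668) and class II (median 0.12, adjusted p 0.483) lost their calls on plain probe sets only. Leaving out 1 severe mouse ended the calls of Gfap (replicate 3, 1.31, adjusted p 0.0657), H2-Aa (replicate 1, 0.84, 0.0578), Tspan17 (replicate 2 or 3, up to 0.062) and C3ar1 (replicate 1 or 5, up to 0.133). It also ended those of Lyz2 (replicate 1 or 2, up to 0.126), Slc7a10 (replicates 1, 2 or 3, up to 0.145), Sez6l (replicates 1, 4 or 5, up to 0.142), Cks2 (replicates 2, 4 or 5, up to 0.178) and the immediate early genes (replicate 1 or 5, up to 0.204). Without 1 young mouse the calls lost were those of C3ar1 and Lyz2 (replicate 2 or 3, up to 0.0613 and 0.0694) and Slc7a10 (replicates 1, 2 or 3, up to 0.0771). Lost too were Sez6l (replicates 1, 2, 4 or 8, up to 0.0656), Cks2 (replicates 2, 6 or 7, up to 0.135) and the immediate early genes (replicates 2, 5 or 8, up to 0.101).

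**Figure D3:**
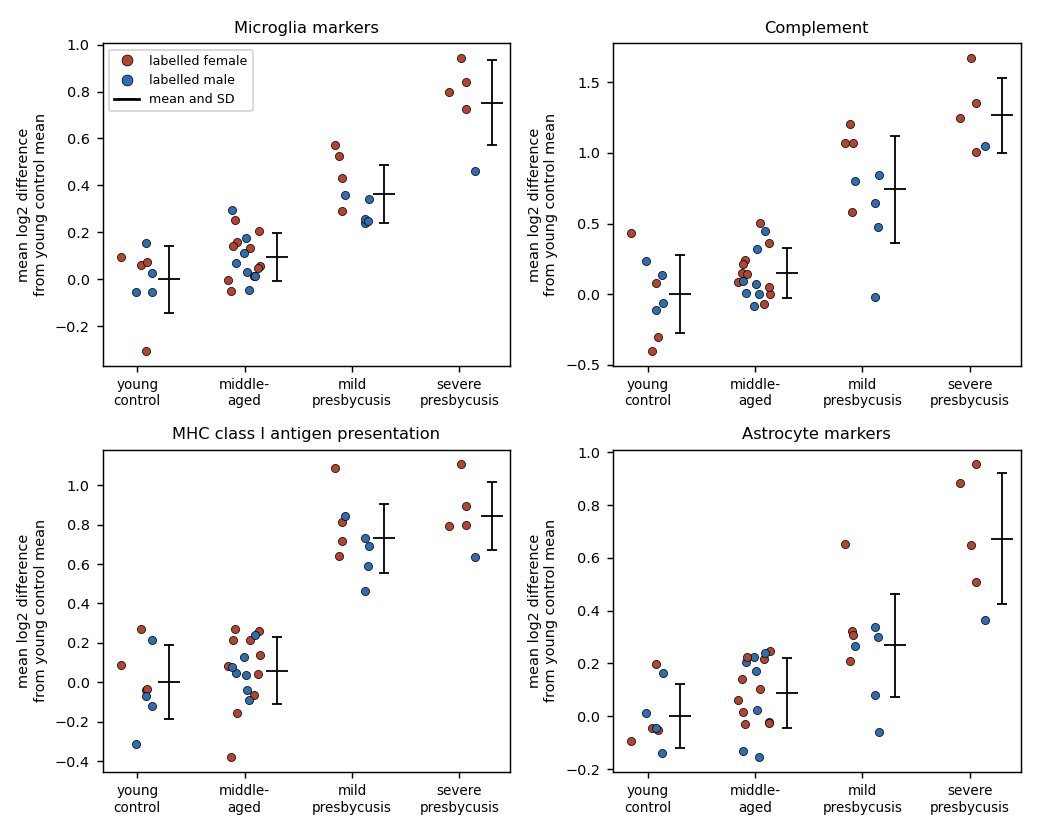
Scores of gene lists per mouse, the mean log2 difference of the genes of a list from the young control mean, with mean and SD per group (points, mice; colour, sex; no adjustment for sex). The microglia score is 0.46 to 0.94 in the 5 severe mice, 0.24 to 0.57 in the 9 mild mice and at most 0.16 in the young controls.

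In an exact two-sided permutation test of these scores, without the sex covariate, all 5 severe mice lay above the highest young mouse for microglia, complement, astrocyte, MHC class I and MHC class II genes. Each of these had p 0.000777, the smallest that 1287 splits allow (adjusted p 0.0053). The microglia and MHC class I scores of all 9 mild mice lay above the highest young score (mean differences 0.36 and 0.73, exact permutation p 4.11e-05, the smallest that 24310 splits allow, adjusted p 7e-04). By the same test the antioxidant enzymes (mean difference 0.17, adjusted p 0.014, 5 of 9 above the highest young mouse) and the astrocyte markers (0.27, adjusted p 0.024, 7 of 9) were higher in mild presbycusis than in young controls. Camera called neither (medians 0.12 and 0.18, adjusted p 0.11 for both).

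Mice with mild presbycusis were compared with middle-aged mice of good hearing. The 25 called probe sets were all higher. Among brighter probe sets the largest rises were those of Lyz1 (1.96, SE 0.37, adjusted p 0.00747), H2-D1 (1.46, SE 0.16, adjusted p 1.24e-06), Rtp4 (1.36, SE 0.25, adjusted p 0.00504) and Mpeg1 (1.19, SE 0.22, adjusted p 0.00651), each in 9 of 9 mice. C1qb rose by 1.00 (SE 0.18), Chil1 by 0.84 (SE 0.13), Clec7a by 0.77 (SE 0.13), Tyrobp by 0.73 (SE 0.15), the lysosomal protease Ctsh by 0.72 (SE 0.13) and H2-Aa by 0.72 (SE 0.15), also in 9 of 9. Of 9 MHC class I genes 4 rose (median 0.40, camera adjusted p 6.42e-21, and 2.44e-07 with an estimated correlation), including the immunoproteasome subunits Psmb8 (1.56, SE 0.19) and Psmb9 (1.21, SE 0.23). Of 12 interferon-stimulated genes 2 rose (median 0.42, adjusted p 7.17e-12, and 0.000286 with an estimated correlation). So did 2 of 16 microglia markers, Cd68 (0.66, SE 0.13, 8 of 9 mice) and Tyrobp (median 0.26, adjusted p 6.28e-10, and 0.000202 with an estimated correlation), and 2 of 6 complement genes, C1qc (1.51, SE 0.22, 8 of 9) and C1qb (median 0.54, adjusted p 6.28e-10, and 0.000202 with an estimated correlation). Lists of MHC class II (median 0.23, adjusted p 0.0266, but 0.163 with an estimated correlation), oxidative phosphorylation (median -0.12, adjusted p 5.54e-07, but 0.116) and immediate early genes (median -0.14, adjusted p 0.00131, but 0.116) lost their calls with an estimated correlation. Within sexes, as labelled, the count was 79 among females and 3 among males. The females include middle-aged replicate 4, whose Eif2s3y and Xist lay within the ranges of males. Lyz1 differed by 3.26 among females alone and by 0.70 among males alone (adjusted p 0.43), and C1qb by 1.60 and 0.44 (adjusted p 0.435). None of the called genes named here passed among males alone. Among females alone Rtp4, Psmb9 and Ifit3 did not pass (adjusted p 0.137, 0.122 and 0.12). The MHC class I gene B2m also lost its call among females alone, and with the arrays centred on their median. With the arrays centred on their median or with quantile normalization the calls of H2-Aa (adjusted p 0.0964 and 0.0598) and Tyrobp (0.0528 and 0.054) were lost, and without the sex covariate those of H2-Aa, Tyrobp and Cd68 (0.054, 0.0564 and 0.064). Oxidative phosphorylation lost its call with quantile normalization (median -0.01, adjusted p 0.354). On plain probe sets only the count of called probe sets was 13, with the MHC class II median at -0.17. The interferon-induced Ifitm3 did not pass in the main fit. It passed with only these 2 groups in the fit (0.70, adjusted p 0.00806), with array weights (0.0253) and among females alone (1.05, 0.0227). It also passed without the 3 arrays with cerebellar signal (0.0455) and without young replicate 5 (0.70, 0.0487).

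Severe presbycusis against middle-aged mice gave 110 called probe sets, 109 higher and 1 lower. The lower call was that of Ifna2, an interferon alpha gene, on a dim probe set (-1.51, SE 0.36, adjusted p 0.0382), named after its values were seen. Lyz1 rose by 3.71 (SE 0.46, adjusted p 1.57e-06), Mpeg1 by 2.57 (SE 0.27, adjusted p 9.95e-08), Tent5c by 2.09 (SE 0.47, adjusted p 0.0172), H2-D1 by 1.94 (SE 0.20, adjusted p 8.14e-08) and Clec7a by 1.70 (SE 0.16, adjusted p 1.2e-08), in 5 of 5 mice. Further rises in 5 of 5 were those of the intermediate filament Vim (1.44, SE 0.35), Lyz2 (1.43, SE 0.30), C1qb (1.42, SE 0.22), Rtp4 (1.38, SE 0.31) and Laptm5 (1.35, SE 0.23). Of 16 microglia markers 7 rose (median 0.63, camera adjusted p 1.8e-27, and 1.98e-08 with an estimated correlation), and of 6 complement genes 4 (median 1.04, adjusted p 6.51e-16, and 2.51e-06). Of 9 MHC class I genes 4 rose (median 0.56, adjusted p 1.28e-17, and 9.02e-07), of 6 MHC class II genes 1 (median 0.39, adjusted p 6.93e-07, and 0.00204) and of 12 interferon-stimulated genes 3 (median 0.59, adjusted p 1.86e-08, and 0.00218). The second of each 2 p-values is that with an estimated correlation. Of 12 astrocyte markers 3 rose (median 0.09, mean 0.57, adjusted p 3.71e-05, and 0.000794 with an estimated correlation): Serpina3n by 3.7 (SE 0.51), Gfap by 1.85 (SE 0.28) and Vim. With dim probe sets left out the astrocyte call was lost (median 0.06, adjusted p 0.208). The 14 heat shock and chaperone genes were lower as a list (median -0.18, adjusted p 0.0204, but 0.0702 with an estimated correlation; Hspa8 -0.45, SE 0.23). So were the immediate early genes (median -0.16, adjusted p 0.0189, but 0.273 with an estimated correlation). Without severe replicate 1 the count was 73 and the calls of Tent5c, Vim, Lyz2, Rtp4, Ifitm3, the heat shock list and the immediate early genes did not pass (adjusted p 0.0831, 0.225, 0.0837, 0.172, 0.175, 0.108 and 0.233). Further calls were lost without severe replicate 2 (Lyz2, Tent5c, Vim and Ifitm3, up to 0.189), 3 (Rtp4, Tent5c, Vim and Ifitm3, up to 0.231), 4 (heat shock list, 0.371) or 5 (Tent5c and Vim, up to 0.138). Vim was also lost without young replicate 5, 6 or 7 (up to 0.0538). In all its call was lost in 12 of 29 alternatives, among them quantile normalization (adjusted p 0.0631), centring of the arrays (0.0528), no trend in the variance (0.0607), leaving out middle-aged replicate 4 (0.0754) and the 3' over 5' covariate (0.0721). On plain probe sets only the calls were lost for MHC class I (median 0.16, adjusted p 0.126) and class II (median 0.27, adjusted p 0.193).

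Severe against mild presbycusis concerns the degree of hearing loss. Of 22626 probe sets 0 were called by limma, with 843 at an unadjusted p under 0.05 where chance gives 1131. The smallest p-values for higher levels were those of Clec7a (0.93, SE 0.18, adjusted p 0.0764), Ptprc (0.80, SE 0.18, adjusted p 0.232) and Mpeg1 (1.38, SE 0.30, adjusted p 0.232), each above the mild mean in 4 of 5 mice. For lower levels they were those of Lypd8 (-0.65, SE 0.19), Flvcr2 (-0.60, SE 0.17) and Ldah (-0.99, SE 0.29), with adjusted p of 1. As lists, microglia markers (median 0.41, camera adjusted p 2.66e-14, and 1.93e-05 with an estimated correlation), complement (median 0.39, adjusted p 6.49e-06, and 0.0047) and astrocyte markers (median 0.08, mean 0.37, adjusted p 0.000458, and 0.0047) were higher in severe presbycusis. MHC class II (median 0.25, adjusted p 0.002) had an adjusted p of 0.0745 with an estimated correlation. Serpina3n differed by 2.48 (SE 0.56, adjusted p 0.315) and C1qa by 1.15 (SE 0.31, adjusted p 1), both higher in 5 of 5. In the exact permutation test of scores none passed. The microglia score had an adjusted p of 0.051 (mean difference 0.39, 4 of 5 severe mice above the highest mild mouse). Severe replicate 4, the 1 male of its group, bears on the count. Without it 11 probe sets were called, among them Clec7a (1.22, adjusted p 0.000135), Mpeg1 (1.86, adjusted p 0.000874) and Ptprc (1.04, adjusted p 0.00235). Without severe replicate 3 the count was 1 and without young replicate 8 it was 2. Clec7a also passed with the arrays centred (adjusted p 0.0343), with a pseudocount of 64 (0.0309), on plain probe sets only (0.0475) and among females alone (0.0484). Mpeg1 and Serpina3n passed with a pseudocount of 64 (0.0488 and 0.0444) and among females alone (0.00219 and 0.0484). The complement call was lost with dim probe sets left out (adjusted p 0.0582). The MHC class II call was lost with dim probe sets left out (0.475), by fry (0.351), on plain probe sets only (0.238) and among females alone (0.161). The astrocyte call was lost without severe replicate 2 (adjusted p 0.07), with dim probe sets left out (adjusted p 0.231) and by fry (adjusted p 0.0579), and the MHC class II call without severe replicate 1 (adjusted p 0.109).

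Across the 4 groups a moderated F-test called 120 probe sets. The calls against young controls overlapped: 35 of the 38 probe sets higher in mild presbycusis were also among the 120 of severe presbycusis. Independent lists of these sizes would share 0.19. In 20 simulations of unchanged groups 0 were shared. Unchanged groups give few calls to share, so these simulations cannot tell how far the common young controls raise the overlap. The young controls were also split into 2 sets of 4, with a separate set for each comparison. Then 4 to 20 probe sets were shared over 36 splits (mean 12.1).

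Between the sexes 11 probe sets were called, 6 higher and 5 lower in males. Kdm5d, a gene of the Y chromosome, was higher by 1.48 (SE 0.13, adjusted p 4.02e-10) in 17 of 17 males. Xist, the RNA that silences 1 X chromosome of females, differed by -3.61 (SE 0.23, adjusted p 1.01e-14) and Eif2s3x, an X-linked gene with a copy on the Y chromosome, by -0.39 (SE 0.06, adjusted p 0.000781). The array of middle-aged replicate 4, labelled female, had Eif2s3y at 9.39 and Xist at 8.60. Both lay within the ranges of males (8.29 to 10.2 and 7.99 to 9.00) and outside those of the other 21 females (4.11 to 4.73 and 11.32 to 13.04). With separate group effects per sex, the mild minus young change differed between males and females for 279 probe sets, 47 with a higher and 232 with a lower change in males. The middle-aged minus young change differed for 0 by limma (1646 at an unadjusted p under 0.05). Of the genes named above as higher in mild presbycusis, Lyz1 (-3.15, SE 0.53, adjusted p 0.00425) and C1qb (-1.44, SE 0.31, adjusted p 0.0121) were among those with a lower change in males. Another C1qb probe set had the smallest adjusted p of all (-2.40, SE 0.35, adjusted p 0.00122). Both C1qb probe sets carry a suffix for shared probes. The mild minus young change itself was called for 606 probe sets in females (4 against 4) and for 6 in males (5 against 4). Without young replicate 5 the count of 279 was 152, and with array weights or with a covariate for a suffix in the array name, whose meaning is not given in the sources used here, it was 89.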

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

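Chosen after the result was seen were the 3 tests of Gabra6, the 2 tests of blood and the test of oligodendrocyte and endothelial markers; the RNA quality tests, the test of neighbouring mouse numbers and the regroupings of the mice were written before their values were seen. A single mouse far from the others of its group was looked for in 240 groups of values (66 genes and 14 lists), and 26 stood apart, where chance alone gives about 1 in 20 groups. Values are log2(intensity + 16) or list scores.

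Among young controls, these values stood far from the others: replicate 8 for C1qc (7.13, others 4.80 to 5.60), replicate 3 for Gabra2 (7.37, others 6.41 to 6.79), replicate 2 for Gabra6 (12.82, others 7.40 to 8.32), replicate 5 for Mpeg1 (5.88, others 7.11 to 7.60) and replicate 4 for Tyrobp (6.76, others 7.57 to 8.21). Replicate 2 also stood apart in the microglia score (-0.30, others -0.06 to 0.16) and the cerebellar score (2.18, others -0.48 to -0.22). In mild presbycusis they were replicate 1 for Abat (10.39, others 11.29 to 11.88), replicate 3 for C1qc (5.75, others 7.18 to 8.17) and for the interferon score (0.98, others 0.29 to 0.61), replicate 2 for H2-Aa (9.65, others 7.89 to 8.70), and replicate 5 for Fmod (9.07, others 7.43 to 7.81), Igf2 (10.14, others 6.1 to 7.55) and Ogn (8.94, others 6.57 to 7.77).

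In severe presbycusis replicate 4, the 1 male of the group, was lower than the 4 females for 9 genes: Cd53 (8.40, others 8.97 to 9.19), Clec7a (8.76, others 10.25 to 10.48), Ctsh (8.30, others 9.37 to 9.79), Hspa8 (11.55, others 12.24 to 12.47), Laptm5 (8.46, others 9.94 to 10.41), Lyz1 (7.78, others 10.93 to 11.86), Mpeg1 (8.79, others 11.05 to 11.34), Tent5c (6.95, others 9.40 to 9.75) and Vim (8.00, others 9.37 to 9.77). With 1 male the design does not separate this mouse from its sex. Replicate 3 was high for Csf1r (12.54, others 11.55 to 11.70), replicate 1 was low for Elmo1 (9.61, others 9.86 to 9.96) and high for the fibroblast, meningeal and collagen score (0.48, others -0.43 to -0.23).

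The change from young controls, which for mild mice does not separate age from hearing loss, differed between the sexes in 3 results: 279 probe sets for mild minus young, the cerebellar list for middle-aged minus young (median difference 0.88, males minus females, adjusted p 0.00413, and 0.702 with an estimated correlation) and the synaptic vesicle and release list for mild minus young (0.39, adjusted p 0.0352, and 0.216 with an estimated correlation). Without the 3 arrays with cerebellar signal (young replicate 2, middle-aged replicates 7 and 8), a setting chosen after seeing the data, the first list stood at -0.08 (adjusted p 0.786) and the second at 0.40 (adjusted p 0.0571).

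The first pattern is the low Gabra6 ratio of the older groups in the authors' deposited table. Other cerebellar markers stood a median of 2.27 above the other young arrays on young replicate 2, and with a geometric instead of an arithmetic mean of the young arrays as the reference the middle-aged ratio was 0.886 instead of 0.207. The fall with age in the authors' deposited table was -2.27 on the log2 scale for middle-aged mice. It lies outside the interval without that array, whose lower bound is -0.36. It is also outside that without middle-aged replicates 7 and 8 as well, whose lower bound is -0.48. With all arrays kept the difference was -0.19 (SE 0.52), far from -2.27 too. The distance from -2.27 thus does not rest on leaving arrays out. A candidate explanation is cerebellar tissue in 1 young sample, weighted up by the arithmetic mean. Smaller changes of Gabra6 with age or hearing loss stay open.

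The second pattern is the rise of microglia markers in severe presbycusis. RNA quality is argued against, since with the 3' over 5' ratio as a covariate the list median was 0.85 (adjusted p 4.73e-26). So is a lower share of neurons that raises all other cell types. The pooled median of oligodendrocyte and endothelial markers was -0.04 (95% interval -0.16 to 0.11) against 0.82 (0.31 to 1.16) for microglia. These intervals, and that of the blood markers below, come from 10000 resamples of the genes. They give the spread between genes and not between mice. Over the severe mice the list scores were 0.02 ± 0.06 (SD) for oligodendrocyte, -0.04 ± 0.25 for endothelial and 0.75 ± 0.18 for microglia markers. A first test of blood by the median of 7 blood markers (0.03, interval -0.05 to 0.40) decided nothing, since 0.40 is not below the lower microglia bound of 0.31. A second test on haemoglobin genes was then chosen with a looser rule, an upper bound below the microglia median of 0.82. The mean haemoglobin difference was -0.03 with an upper bound of 0.45, which met this rule but not that of the first test. The haemoglobin difference thus lay below the microglia median, but by the stricter rule whole blood as the sole cause stays undecided. A larger number or a changed state of microglia with age or with hearing loss may account for the rise, and so may white blood cells without red cells; neither was tested.

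The third pattern is the sex difference of the mild minus young change. With the 3' over 5' ratio as a covariate 317 probe sets were called, so that RNA quality as this ratio reads it does not explain the count. Whether mice with neighbouring numbers were handled together cannot be told apart from the data, since their residual correlation was 0.011 against -0.001 for the others (permutation p 0.198). With a covariate for a suffix in the array name, chosen after seeing the data, the count was 89, which leaves what the suffix stands for as a candidate explanation for part of it; its meaning is not given in the sources used here. A difference between the sexes in the change with age or with hearing loss stays open and was not tested further. In the comparison with good hearing in both groups, middle-aged minus young, 0 probe sets were called for a sex difference.

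Other splits of the same mice into groups of the same sizes, 100 for each result with the real one included, asked how often a split called as many. The cut, set before the values were seen and not adjusted over the results, was under 5 of the 100 splits. Under the cut were the counts of probe sets in mild against young (38, highest other 631, 2 splits with as many) and severe against young (120, highest other 154, 2 splits). So was mild against middle-aged (25, highest other 46, 2 splits). In these comparisons another split called more than the real one, so chance can give such counts. With the real split alone (1 split) were severe against middle-aged (110, highest other 12), the F-test (120, highest other 2) and the sexes (11, highest other 1). The sex difference of the mild minus young change was such a result too (279, highest other 123). Middle-aged against young (1, highest other 2, 9 splits) was not under the cut. For severe against mild (0, highest other 127) and the sex difference of the middle-aged change (0, highest other 5) the splits say nothing, since with a real count of 0 all 100 splits have as many. The splits with 631 and 127 calls may reflect a structure of the samples other than group, which was not tested. The number of called lists was under the cut in mild against young (10, highest other 12, 2 splits) and mild against middle-aged (7, highest other 8, 4 splits). It was not in middle-aged against young (1, highest other 5, 55 splits) and severe against young (8, highest other 11, 13 splits). Nor was it in severe against middle-aged (8, highest other 8, 5 splits) and severe against mild (4, highest other 7, 17 splits). The results with 4 and 5 splits lie next to the cut and hardly differ.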

How the results depend on the processing

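Chosen after seeing the data were the results without the 3 arrays with cerebellar signal, with the array name suffix or the 3' over 5' ratio as a covariate, without middle-aged replicate 4, and by permutation of list scores. No paired analysis was possible because the mouse numbers are unique to each group. The microglia list kept its call under all alternatives but 1 (severe against young: 33 camera or fry alternatives, median 0.74 to 0.91, highest adjusted p 5.15e-08), the exception being the permutation of list scores in severe against mild (adjusted p 0.051). The complement list against young and middle-aged mice and the interferon list kept theirs under all. Of the called genes, over all alternatives, 2496 values stayed on their side of the threshold with the same direction and 179 did not pass; of the called lists 1162 stayed, 108 did not pass and 2 changed direction in the test. The medians of 8 changed sign, 0 of them with an adjusted p that passed. Of the counts 332 stayed within 1.5 times and 53 did not.

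The 2 lists that changed direction were MHC class II in mild against middle-aged mice on plain probe sets only (-0.17) and cerebellar markers in mild against young mice without the 3 arrays with cerebellar signal (0.09). Counts of probe sets that moved by more than 1.5 times are given by setting. Arrays centred on their median: middle-aged against young 0, mild against young 20, severe against mild 2, overlap 19. Quantile normalization: severe against mild 1. Pseudocount 64: severe against mild 5. Dim probe sets left out: sexes 7, sex difference of the mild change 455. No sex covariate: severe against mild 1. Only the 2 groups compared, which leaves fewer samples: mild against young 20, severe against young 43. Array weights: mild against middle-aged 44, severe against mild 2, sex difference of the mild change 89. Plain probe sets only, which tests fewer probe sets: mild against young 20, severe against young 68, mild against middle-aged 13, severe against middle-aged 68, severe against mild 2, F-test 72, overlap 17, sex difference of the mild change 95. Females alone: middle-aged against young 10, mild against young 464, severe against young 247, mild against middle-aged 79, severe against mild 6, F-test 304, overlap 144, GABA genes 3. Males alone: middle-aged against young 2, mild against young 7, mild against middle-aged 3. Deposited RMA table: GABA genes 1. Without the 3 arrays with cerebellar signal: mild against young 25, sex difference of the middle-aged change 1. Array name suffix as a covariate: severe against mild 1, sex difference of the mild change 89. Called lists were 38 in all, 24 with an estimated correlation and 22 by permutation. Except where a smaller number of samples or probe sets is named, the cause was not tested.

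Leaving out 1 severe or 1 young mouse at a time gave 0 to 2 calls for middle-aged against young, 24 to 45 for mild against young, 92 to 133 for severe against young, 25 to 33 for mild against middle-aged, 73 to 130 for severe against middle-aged and 0 to 11 for severe against mild. The F-test gave 96 to 130, the sexes 10 to 12, the overlap 23 to 41, the GABA genes 0 to 1, the lists 33 to 41, and the sex differences 0 to 1 for the middle-aged and 152 to 357 for the mild change. As deposited, with quantile normalization and with centring, the median difference of all probe sets lay between -0.053 and 0.04, and at least 90.3 percent of the calls of each comparison with any were higher. Dim probe sets lie near background, where the pseudocount compresses differences.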

Other observations

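The counts and scores of ribosomal protein genes and the checks of equal values, spread and correlation in the RMA table were chosen after the data were seen; the sex by group interaction and the fit of the GABA genes on the RMA table were fixed before. Besides Lyz1 and C1qb, the genes whose mild minus young change was lower in males than in females included Rpl35 (-1.67, SE 0.37, adjusted p 0.0129) and Rpl11 (-1.48, SE 0.27, adjusted p 0.00474) of the large ribosomal subunit, Rps14 of the small 1 (-1.53, SE 0.40, adjusted p 0.0416), and Pfdn5, a subunit of a cytosolic chaperone (-1.78, SE 0.38, adjusted p 0.0099); these were named after their values were seen. Of 45 measured ribosomal protein genes 4 were called lower and 0 higher on the brightest probe set of each gene, against 141 and 27 of 12393 genes, and 9 were called lower on any probe set. Their median mild minus young change was 0.23 in females and -0.08 in males. The brightest probe sets of Rpl35 and Rps14 carry a suffix for shared probes, so their signal may not be that of these genes alone. The ribosomal score was -0.16 ± 0.07 (SD) in the 4 young females, 0.09 ± 0.22 in the 4 young males (replicate 6 at 0.39, the others at -0.08 to 0.10), 0.04 ± 0.08 in the 4 mild females and -0.01 ± 0.12 in the 5 mild males.

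In the deposited RMA table the brighter Gabarapl1 probe set and a Gabbr1 probe set hold exactly the same value on 30 of 39 arrays. The cause, such as saturation or an error in the table, is not given in the sources used here, and what the RMA values of these 2 probe sets measure stays open. The log2 values of this Gabarapl1 probe set have an SD of 0.01 there and of 1.45 in the scaled intensities, and over the named probe sets the 2 kinds of values correlate with a median of 0.59 (0.04 to 0.97). The second Gabra6 probe set has ratios of 0.479, 0.488 and 0.451 for middle-aged, mild and severe mice in the authors' deposited table, and Gabrd, another subunit of cerebellar granule cells, has 0.814, 0.783 and 0.745. Without young replicate 2 these ratios were 1.05, 1.07 and 0.988 for Gabra6 and 1.02, 0.984 and 0.936 for Gabrd. Refitted with limma on the RMA signals, 0 of the 33 probe sets were called in the 3 comparisons against young controls; Gabarap was called in severe against middle-aged mice (0.26, adjusted p 0.0474).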
